A study of Mus musculus with 6 samples.

How the data were processed

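Gene expression was measured in 6 cultures of primary mouse dermal fibroblasts, 3 treated with 5-aza-2'-deoxycytidine and 3 untreated, with 1 Affymetrix expression array per culture. Per the labels' protocols, total RNA was extracted with a column kit, labelled with biotin by in vitro transcription and hybridised by the manufacturer's standard procedures. The deposited values are MAS5 signal intensities, one per probe set and array, per the submitters' processing notes, which name MAS5. MAS5 computes a background-corrected signal from the pairs of perfect-match and mismatch probes of a probe set. Its version, its target intensity and its detection calls are not given in the sources used here. The deposited table was linear and held no negative value. Its 2% trimmed means ranged from 149.2 to 223.9 signal units between arrays, so the deposited signals had not been brought to a common level.

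Each array was multiplied by a factor that set its 2% trimmed mean to 193.2 signal units, the mean over the 6 arrays. Signals were then transformed to log2(signal + 9.66), where the pseudocount is 0.05 of that trimmed mean. Every log2 change below is on this scale and is treated minus control, and it understates the change of probe sets with low signal. The 64 control probe sets of the manufacturer were left out of the test. A probe set was tested if its signal exceeded the median of its array on at least 3 of the 6 arrays, whichever group they belonged to. This left 23388 of 45037 probe sets. A probe set that was dim in all controls could pass through the treated arrays alone, and the reverse, so counts in lists of mostly dim genes favour members that changed. Without detection calls, a low signal was not separated from background, and the number of arrays limits the precision.

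Treated and control arrays were compared with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, with the group as the sole term, as a two-sided test. P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, and adjusted p-values under 0.05 were called. The standard error of a log2 change is the moderated one from this fit. Groups came from the sample titles. The description of the design says that cells were explanted separately for each biological replicate. Treated and control cultures carry the same replicate numbers, and whether a number stands for a shared explant is not given in the sources used here. The replicate number was therefore not a term of the fit.

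Probe sets were named through the platform annotation supplied with the table. Outside the controls, 34945 probe sets named 1 gene, 932 named several and 9160 had no gene listed there. Of the named probe sets, 34754 matched a gene of the mouse assembly GRCm38.p6 by Entrez identifier, and 0 symbols changed. That assembly was used for names, chromosomes and the order of genes. No gene was named from a probe set with several genes. A gene was represented by its tested probe set with the highest mean log2 signal over the 6 arrays, which gave 12194 genes. Of these, 5218 had more than 1 tested probe set, and 67 had probe sets called in opposite directions.

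Before the data were examined, 27 gene lists with 589 entries were fixed, along with the tests, the alternatives and the rule for naming genes. The arrays held 522 of the entries and 386 were tested. The 26 lists with at least 5 tested members were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists. As alternatives, the correlation was estimated for each list, and fry tested whether the members of a list moved on balance in one direction. For each list the members called were counted after adjustment over all probe sets and after adjustment over the list alone. Chromosomes with at least 20 tested genes were tested with camera in the same way. A probe set was counted as switched on when it lay below the 40th percentile of the array on all 3 control arrays and above the median on all 3 treated arrays, and as switched off in the opposite case.

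The rule for naming took, in each direction, the 12 genes with the largest log2 change among those called whose 3 treated arrays all lay on one side of the 3 control arrays. Genes named by a clone or model number were passed over. The rule also took up to 4 members of each list, those with the smallest p, and 18 genes whatever their values: Dnmt1, Dnmt3a, Dnmt3b, Uhrf1, Cdkn1a, Mki67, Xist, H19, Igf2, Myod1, Dazl, Sycp3, Mael, Col1a1, Col3a1, Acta2, Actb and Gapdh. Other list members appear in the text as examples within a list, and they and any gene outside the lists were chosen after their values were seen.

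The procedure was tested on simulated arrays with the 23388 probe sets of this comparison, with 200 probe sets changed in each of 10 runs. It recovered 32.8% of probe sets changed 1.5-fold, 72.2% of those changed 2-fold and 94.7% of those changed 4-fold, and 7.9% of its calls were false. It called 10 of 10 lists of 20 genes shifted by 0.5 on the log2 scale and 0 of 270 unshifted lists. Genes were simulated as independent of one another, so the list result does not cover lists of correlated genes. The 200 changed probe sets were also far fewer than the 9040 called in the data, so these rates need not carry over.

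The alternatives were quantile normalization, the deposited signals without scaling, pseudocounts of 0.01 and 0.2 of the trimmed mean, no filter, a filter on the mean signal, eBayes without the trend, the replicate number as a block, leaving out probe sets whose names mark probes shared between transcripts, the mean of a gene's probe sets, other thresholds for switched probe sets and leaving out each array in turn. Gene families by symbol stem, counts of list and family members with no filter, and counts of list members in other settings, were added after the data had been seen. Dates of hybridisation and scanning are not given in the sources used here, so no batch could be tested.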

Results

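The data were expression profiles of primary dermal fibroblasts, the matrix-producing cells of the skin, grown from explants of neonatal mice and used at passage 4. In 3 cultures 5-aza-2'-deoxycytidine was present at 5 µM during 96 hours, renewed every 24 hours, and the cells were then kept for 24 hours in medium without drug. The other 3 cultures were untreated controls. 5-aza-2'-deoxycytidine (decitabine) is a cytidine analogue that is built into DNA and traps DNA methyltransferases, so that methylation is lost as cells divide. The comparison asks which transcripts differ after this exposure, and each group has n = 3 arrays. The trimmed mean of the deposited signals was 223.9, 179.1 and 189.9 on control arrays 1 to 3 and 149.2, 207.9 and 209.4 on treated arrays 1 to 3. After scaling, correlations of log2 signals lay between 0.972 and 0.974 within groups and between 0.863 and 0.883 across groups. The ratio of the 3' to the 5' control probe set of Actb, a measure of RNA integrity and labelling, was 1.26 ± 0.010 (SD, n = 3) in controls and 1.16 ± 0.019 in treated cultures (exact permutation test, two-sided, p = 0.1, the smallest p that 3 against 3 allows). The same ratio for Gapdh was 0.739 ± 0.016 and 0.764 ± 0.024 (exact permutation p = 0.2).

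The named genes with the highest changes included genes known from germ cells, placenta and epidermis, and many of those with the lowest changes encode secreted and matrix proteins. Asb5, an ankyrin repeat protein of ubiquitin ligase complexes, had the largest rise of the named genes, from a signal of 11.8 ± 4.13 (SD, n = 3) to 5116 ± 267, a log2 change of 7.92 ± 0.14 (SE; adjusted p = 3.85e-09). The germ-cell RNA-binding protein Dazl rose from 20.5 ± 8.34 to 802 ± 35.2, and the meiotic recombination gene Mnd1 from 2.83 ± 1.66 to 304.6 ± 35.4. Prl8a9 and Prl8a6, placental members of the prolactin family, rose by log2 4.64 ± 0.23 and 4.36 ± 0.24. Afp, a serum protein of fetal liver and yolk sac, went from 0.502 ± 0.284 to 317 ± 2.50. The protease inhibitors Serpinb2 (log2 change 5.07) and Serpinb9b (4.53), the semaphorin Sema3e (4.56), the cornified envelope gene Crct1 (4.37), the simple epithelial keratin Krt18 (4.36) and the transglutaminase Tgm2 (4.32) completed the 12 highest. Of these 12, 8 were switched on from below the 40th percentile of every control array, where the size of a fold, and so the order of the genes, depends on the pseudocount.

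The lowest change belonged to Agtr2, an angiotensin receptor, whose signal went from 1751 ± 188 to 13.9 ± 10.3 (SD, n = 3), a log2 change of -6.34 ± 0.32 (SE; adjusted p = 6.94e-07). The microfibril protein Mfap4 went from 1250 ± 323 to 7.46 ± 3.06, and pleiotrophin (Ptn), a heparin-binding growth factor, from 10478 ± 787 to 141.9 ± 44.0. Treated signals of Agtr2 and Mfap4 were near the pseudocount, as were those of Egfl6 (mean 13.9) and Angptl1 (4.67), listed next. The order of these genes depends on the pseudocount. Several others of the 12 lowest are secreted or matrix proteins: Ccn3 (-5.30), Abi3bp (-5.23), Egfl6 (-5.01), the fibrillin Fbn2 (-4.89), Angptl1 (-4.71) and the small proteoglycan asporin, Aspn (-4.61). Lrrc17 (-5.08), the receptor tyrosine kinase Epha3 (-4.63) and the growth arrest gene Gas1 (-4.62) made up the rest.

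**Figure D1:**
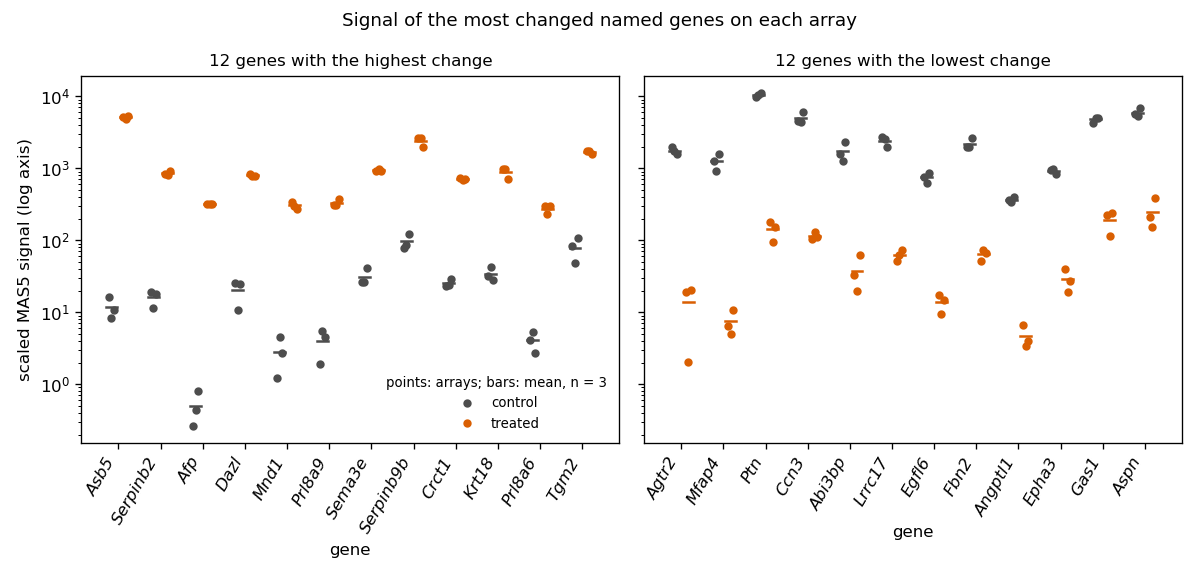
Scaled MAS5 signal on each array, on a log axis, for the 12 named genes with the highest and the 12 with the lowest log2 change; points are arrays, bars are group means (n = 3). In each gene the 3 treated arrays lay on one side of the 3 control arrays, and the signal of Asb5 went from a mean of 11.8 to 5116.

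By limma, 9040 of 23388 tested probe sets passed an adjusted p of 0.05, which is 38.7%; 4297 were higher and 4743 lower in treated cultures. Counted by the representing probe set of each gene, 5008 of 12194 genes passed, 2378 higher and 2630 lower. At least a 2-fold change was found for 657 genes that rose and 738 that fell. In 52.5% of the genes tested the groups did not overlap, where chance gives 10%. With the deposited signals left unscaled, 5019 probe sets passed, 1977 higher and 3042 lower. After scaling, 2738 of the 23388 tested probe sets had no single gene listed, and 420 of these were called higher and 352 lower.

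Several germline genes rose. The filter on dim probe sets left 8 of 32 germline genes on the array, and 5 of these 8 lay below the array median in every control, so that they could pass the filter through the treated arrays alone. Of the 8 tested members of the list, 6 rose and 0 fell, both over all probe sets and adjusted over the list alone, with a median log2 change of 2.23 (camera adjusted p = 0.00115; adjusted p = 0.154 with an estimated correlation). With no filter, 8 of 32 rose and 1 fell, and the median was 0.27 (camera adjusted p = 0.0339; adjusted p = 0.222 with an estimated correlation). Besides Dazl, the tested risers were Tex19.1, a repressor of retrotransposons in germ cells and placenta (log2 change 3.36 ± 0.15, SE), the germ-cell transcription factor Taf7l (2.41 ± 0.23), the meiotic gene Tex15 (2.15 ± 0.27), Slc25a31 (2.31) and Asz1 (0.84). Sycp3 and Mael did not pass the filter on dim probe sets and were not tested. In the trophoblast list 4 of 6 tested members rose and 0 fell, with 4 and 1 adjusted over the list alone. These were the homeobox genes Rhox5 (4.02 ± 0.29), Rhox6 (2.34) and Rhox9 (0.99), and Psg23 (0.93). The probe set of Psg23 has a name that marks probes shared between transcripts. The list as a whole had an adjusted p of 0.101. It passed without scaling (adjusted p = 0.00139) and with no filter, where 5 of 13 rose and the median fell from 0.96 to 0.54 (adjusted p = 0.046). With an estimated correlation it did not pass, with the filter (adjusted p = 0.472) or without (adjusted p = 0.326). In the pluripotency list 1 of 6 rose, Dppa2 (2.75 ± 0.44), and the list was not called (adjusted p = 0.295). With no filter 1 of 15 rose and 0 fell.

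Imprinted genes, which are expressed from 1 parental allele in some or all tissues, fell more often than they rose. The arrays did not measure from which allele a transcript came. Among 28 tested, 14 fell and 3 rose, with the same counts adjusted over the list alone, and the median log2 change was -0.42 (camera adjusted p = 0.000925; adjusted p = 0.102 with an estimated correlation). With no filter 13 of 35 fell and 4 rose (median -0.26; adjusted p = 0.00227; adjusted p = 0.108 with an estimated correlation). Without scaling 12 of the 28 fell and 1 rose. Mest fell from 1268 ± 60.1 to 154.3 ± 17.4 (SD, n = 3). Plagl1 (-2.73 ± 0.11, SE), Dlk1 (-2.81 ± 0.13), Peg3 (-2.22 ± 0.081) and the growth factor Igf2 (-2.63 ± 0.21) also fell. Gatm (2.20), Asb4 (1.00) and Impact (0.62) were the 3 that rose. H19 had no probe set named here.

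Matrix genes fell. Of 25 tested members of the extracellular matrix list, 19 fell and 1 rose, with 20 and 1 adjusted over the list alone, and the median log2 change was -0.85 (camera adjusted p = 8.69e-08; adjusted p = 0.393 with an estimated correlation). The collagen VI chains Col6a2 and Col6a1 changed by -3.35 ± 0.13 and -3.01 ± 0.15 (SE), Col6a3 by -2.22 ± 0.097 and the elastic fibre protein Fbln5 by -2.25 ± 0.11. Col1a1 fell from 6268 ± 645 to 1924 ± 252 (SD, n = 3) and Col3a1 from 10388 ± 952 to 3007 ± 292. A dimmer probe set of Col3a1 changed by -4.10, and the dimmer one of Col1a1 by -0.44 (adjusted p = 0.0765). The member that rose was fibronectin, Fn1 (0.26), and without control replicate 1 or 2, or treated replicate 1 or 3, 0 members rose. Alongside, contractile and pericyte genes moved in part the other way: 5 of 11 rose, the same count as adjusted over the list alone, among them Actg2 (2.20 ± 0.098), Cnn1 (1.55 ± 0.10) and the adhesion molecule Mcam (2.56 ± 0.19), while the receptor Pdgfrb fell (-1.35 ± 0.15). That list missed the threshold (adjusted p = 0.0567; adjusted p = 0.393 with an estimated correlation), and passed it in 7 other camera settings, with adjusted p-values from 0.00839 without scaling to 0.0468 with the filter on the mean signal, among them those without control replicate 2 (adjusted p = 0.0388) or treated replicate 2 (adjusted p = 0.0386). The main probe set of Acta2 changed by 0.17 ± 0.094 (adjusted p = 0.182; 0.12 with adjusted p = 0.0361 after quantile normalization), and a dimmer one by 1.38. The lower Actb 3' to 5' ratio of treated cultures stands beside these changes.

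Genes of cell division fell and p53 target genes rose. In the mitosis list 21 of 25 tested members fell and 0 rose, with 22 and 0 adjusted over the list alone (median log2 change -0.87; camera adjusted p = 3.74e-07; adjusted p = 0.393 with an estimated correlation). The B-type cyclin Ccnb2 changed by -1.79 ± 0.16 (SE), the proliferation marker Mki67 by -1.66 ± 0.19, the spindle protein Nusap1 by -1.38 ± 0.18 and the centromere histone Cenpa by -1.35 ± 0.13. DNA replication genes were not called as a list (9 of 22 fell and 1 rose, the same adjusted over the list alone; adjusted p = 0.260), and 5 fell without control replicate 1 and 4 without scaling. The riser was Rrm2, a subunit of ribonucleotide reductase (1.12 ± 0.14). Among 28 tested p53 targets, 17 rose and 3 fell, with 21 and 4 adjusted over the list alone (median 0.55; camera adjusted p = 5.67e-05; adjusted p = 0.1003 with an estimated correlation). The apoptosis gene Pmaip1 changed by 3.02 ± 0.13, the desmosome-associated Perp by 2.90 ± 0.22, the p53 ubiquitin ligase Mdm2 by 2.08 ± 0.097 and the cell cycle inhibitor Cdkn1a by 1.02 ± 0.094. The 3 that fell were Sesn1 (-1.28), Sesn2 (-0.45) and Zmat3 (-0.40).

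Secreted factors linked to senescent cells rose. In that list 15 of 21 tested members rose and 3 fell, with the same counts adjusted over the list alone (median 1.42; camera adjusted p = 5.95e-05; adjusted p = 0.393 with an estimated correlation). The chemokine Ccl2 went from 603.4 ± 30.3 to 6864 ± 1140 (SD, n = 3), the matrix protease Mmp10 from 48.2 ± 6.64 to 732 ± 157 and the macrophage growth factor Csf1 from 1822 ± 98.0 to 6272 ± 259. Those that fell were Igfbp3 (-4.05 ± 0.23, SE), Hgf (-1.78) and Igfbp5 (-1.56). The cell cycle inhibitor Cdkn2b rose (0.61), and Cdkn2a changed by -0.01 without passing the test.

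Genes of the oxidative stress response rose: 10 of 11 tested members rose and 0 fell, as also when adjusted over the list alone (median 1.80; camera adjusted p = 8.69e-08; adjusted p = 0.1003 with an estimated correlation). Heme oxygenase Hmox1 went from 715 ± 126 to 4324 ± 302 (SD, n = 3), and thioredoxin reductase Txnrd1 (1.54 ± 0.079, SE), the glutathione synthesis enzyme Gclc (2.10 ± 0.13) and the autophagy receptor Sqstm1 (1.20 ± 0.080) also rose. Cholesterol synthesis genes fell: 16 of 17 fell and 1 rose, as also when adjusted over the list alone (median -0.98; camera adjusted p = 6.13e-08; adjusted p = 0.102 with an estimated correlation). Hmgcs1 changed by -1.79 ± 0.080, Idi1 by -1.62 ± 0.11, Cyp51 by -1.50 ± 0.083 and Fdft1 by -1.31 ± 0.086, and Sc5d was the member that rose (0.31). In the integrated stress response list 8 of 15 fell and 2 rose, the same adjusted over the list alone, among them Herpud1 (-1.13 ± 0.093) and Trib3 (-1.16 ± 0.17). Without scaling, control replicate 2 or 3, or treated replicate 1, 1 member rose. That list was not called by camera (adjusted p = 0.101; adjusted p = 0.393 with an estimated correlation), but passed camera with no filter (adjusted p = 0.0415) and fry (adjusted p = 0.00379).

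Of the DNA methylation machinery, 3 of 13 tested members fell and 1 rose, with 5 and 1 adjusted over the list alone, and the list was not called (adjusted p = 0.295). The call of the faller Zbtb33 (-0.25) was lost on leaving out any 1 array, with quantile normalization and without scaling, and that of the riser Mbd1 (0.72) without scaling (adjusted p = 0.0587). The de novo methyltransferase Dnmt3a fell from 193.3 ± 41.5 to 70.7 ± 3.99 (SD, n = 3). The maintenance methyltransferase Dnmt1 changed by -0.33 ± 0.14 (SE; adjusted p = 0.0961) at its brightest probe set and by -0.99 (adjusted p = 0.00216) at a dimmer one. Dnmt3b changed by 0.06 ± 0.21 (adjusted p = 0.845), with -0.94 (adjusted p = 0.0193) at its other probe set. Uhrf1, which guides Dnmt1 to replicated DNA, changed by -0.62 ± 0.22 (adjusted p = 0.052). Without control replicate 3 the change of Uhrf1 was -0.88 (adjusted p = 0.00391), and it also passed with the larger pseudocount (adjusted p = 0.0497) and the filter on the mean signal (adjusted p = 0.0457).

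Interferon response genes went both ways: 4 of 27 rose and 4 fell, the same adjusted over the list alone, and the list was not called (median -0.07; adjusted p = 0.999). Without treated replicate 2, 7 rose and 3 fell, without treated replicate 3, 3 rose and 7 fell, and without control replicate 1 or 3 or treated replicate 1, 2 fell. The chemokine Cxcl10 rose (2.09 ± 0.20, SE), as did Irgm1 (0.76) and Oas1a (0.73), while the GTPase Iigp1 fell (-1.50 ± 0.12). In antigen presentation 3 of 11 rose and 1 fell, the same adjusted over the list alone, with H2-K1 (0.88), H2-D1 (0.81) and B2m (0.40) higher and Psme1 (-0.53) lower (adjusted p = 0.609). Its median (-0.08) and mean (0.06) differed in sign. The probe sets of H2-K1 and H2-D1 have names that mark probes shared between transcripts, so they may not be separate readings. Without scaling, B2m, Psme1 and Oas1a lost their calls (adjusted p = 0.159, 0.0522 and 0.0596). Of 21 Hox genes 4 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.609), with Hoxd8 (-1.60), Hoxc8 (-1.23) and Hoxa9 (-0.97) lower and Hoxc5 (1.01) higher. Without treated replicate 1, 2 rose, and without scaling 1 did. Of 19 ribosomal protein genes 1 rose, Rpl12 (0.34), and 0 did when adjusted over the list alone (adjusted p = 0.692). The call of Rpl12 was lost on leaving out any 1 array, with changes from 0.26 to 0.39. After quantile normalization 6 of the 19 fell and 2 rose, among the fallers Rps15 (-0.35, adjusted p = 0.000687) and Rpl4 (-0.20, adjusted p = 0.0094). Actb changed by 0.22 ± 0.10 (adjusted p = 0.123; 0.18 with adjusted p = 0.0149 after quantile normalization), and Gapdh is represented by control probe sets that were not part of the test.

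Markers of other cell types were tested because explant cultures can hold such cells, and none of the lists named next was called by camera with the scaling and filter used throughout. Of these lists, keratinocyte and cartilage passed without scaling (adjusted p = 0.0295 and 0.0248) and skeletal muscle with the filter on the mean signal (adjusted p = 0.0468), while with an estimated correlation the adjusted p-values of these lists were 0.393, 0.393 and 0.638. With no filter 0 of them passed, and the medians of skeletal muscle (-0.05) and neuron (0.07) changed sign. The filter left out many dim members of these lists. Without it, 5 of 30 skeletal muscle genes rose and 1 fell, and 3 of 18 keratinocyte genes rose and 0 fell. In the same setting 4 of 15 neuronal genes rose and 3 fell, and 3 of 20 leukocyte genes rose and 0 fell. Risers and fallers there were 1 and 2 of 13 adipocyte genes, and 2 and 0 of 13 endothelial genes. In the keratinocyte list 2 of 9 rose and 0 fell, the same adjusted over the list alone (adjusted p = 0.212). These were involucrin, Ivl (3.79 ± 0.28, SE), and the desmosomal protein Dsp (2.91 ± 0.39), while Krt5 changed by 0.44 ± 0.39 (adjusted p = 0.413). In the skeletal muscle list 4 of 10 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.260), with the actin Acta1 (3.05 ± 0.12) and Des (0.99) higher and the transcription factor Mef2c lower (-2.96 ± 0.22). Myod1 did not pass the filter. In the cartilage and bone list 5 of 9 fell and 0 rose, the same adjusted over the list alone (adjusted p = 0.101), with Col11a1 at -2.51 ± 0.15, Col2a1 at -1.89 and Sox9 at -1.49. Without treated replicate 2 that list passed (adjusted p = 0.0431), while 3 fell without scaling, without any 1 control or without treated replicate 3, and with no filter 3 of 15 fell and the median went from -0.79 to -0.00. The adipocyte list had 2 risers and 2 fallers among 8, or 3 and 2 adjusted over the list alone, with lipoprotein lipase, Lpl, at -3.58 ± 0.20. Without control replicate 1 there were 0 risers and 1 faller, without control replicate 2 there were 0 and 2, and without treated replicate 2 or 3, or scaling, 1 and 2. Its median (0.38) and mean (-0.20) differed in sign, and camera gave it an upward direction (adjusted p = 0.890).

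Neuronal genes rose in 3 and fell in 2 of 7 cases, the same adjusted over the list alone, with Uchl1 at 2.78 ± 0.11 (SE), Nefm at 2.16, Gap43 at -1.29 and Scg2 at -2.11 (adjusted p of the list 0.609, median -0.10, mean 0.27). Endothelial genes rose in 3 and fell in 1 of 8 cases, the same adjusted over the list alone (adjusted p = 0.296). Esam changed by 1.97 and Flt1 by 1.61, with Flt1 signals of 80.3, 16.6 and 99.9 on control arrays 1 to 3. Without treated replicate 1, 1 rose and 0 fell, with Flt1 at 1.54 (adjusted p = 0.0584), and the calls of Cdh5 and Tek were lost in several other settings: 2 rose and 0 fell without control replicate 1 or 3 or treated replicate 3, and 2 and 1 without treated replicate 2. Leukocyte genes rose in 2 of 9 cases, the same adjusted over the list alone (adjusted p = 0.162; 3 without control replicate 2, treated replicate 1 or treated replicate 2), namely Cd53 (1.65) and Cd68 (1.08). Of 9 melanocyte and Schwann cell genes, Mbp rose (0.93) and Pmel fell (-1.22), with 1 and 0 adjusted over the list alone (adjusted p = 0.609). With the mean of the gene's probe sets Mbp changed by 0.26 and lost its call (limma adjusted p = 0.353). Pmel lost its call without control replicate 2 (-1.09) or 3 (-1.18) and without treated replicate 1 (-1.31) or 3 (-0.75). Of the Y-linked genes, Uty changed by -1.04 ± 0.35 (adjusted p = 0.0391), Eif2s3y by -0.99 ± 0.38 (adjusted p = 0.0656) and Kdm5d by -0.93 ± 0.46 (adjusted p = 0.142). Adjusted over the list alone, 2 of these 3 passed. The call of Uty was lost without any 1 array other than control replicate 3, with changes from -0.80 to -1.18, and without control replicate 3 Eif2s3y (-1.53, adjusted p = 0.000217) and Kdm5d (-1.52, adjusted p = 0.00441) passed. The brightest probe set of Xist changed by -0.39 ± 0.16 (adjusted p = 0.0877) and another by -1.02 (adjusted p = 0.00798). Control replicate 3 stood apart from the other controls in these genes. On control arrays 1 to 3 the signals were 202, 211 and 79 for Uty, and 358, 332 and 105 for Eif2s3y. They were 144, 143 and 36 for Kdm5d, and 550.5, 544 and 856 for the brightest probe set of Xist. The labels give the sex of the donor animals as mixed. In control replicate 3, low Y-linked signals went with a high Xist signal, the pattern of a larger female share. On treated arrays 1 to 3 the brightest probe set of Xist read 485, 509 and 457, below every control, beside low Y-linked signals. These values argue against a larger female share as the sole cause of the lower Y-linked signals. A differing mix of sexes combined with a change with treatment cannot be told apart from a change with treatment alone.

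**Figure D2:**
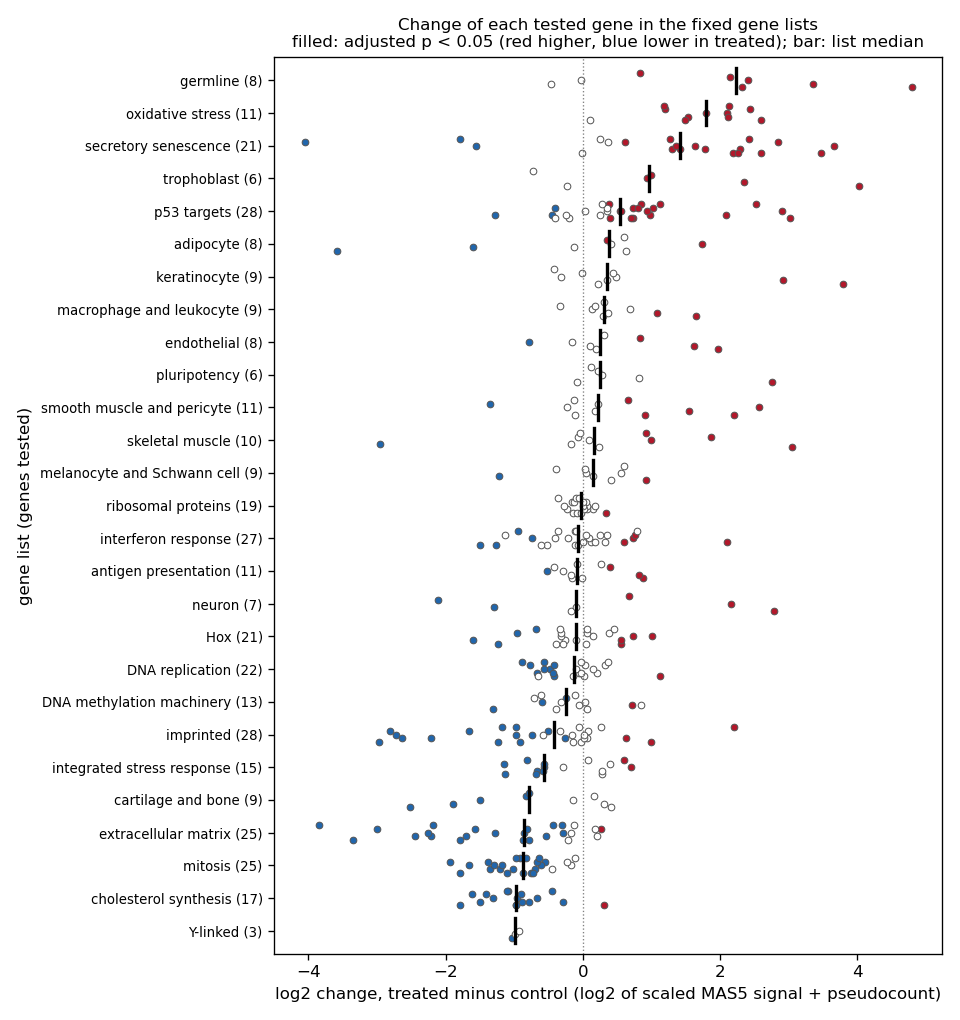
Log2 change, treated minus control, of each tested gene in the 27 fixed lists (points; filled where the adjusted p was below 0.05) with the list median (bar) and the number of genes tested in parentheses. The 8 germline genes past the filter had a median of 2.23, against 0.27 over all 32 with no filter, and the matrix, mitosis and cholesterol synthesis lists had medians of -0.85, -0.87 and -0.98.

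By camera, 8 of 26 lists passed, 4 upward and 4 downward, and with an estimated correlation 0 did, while 20 passed by fry, which asks whether a list moves without comparing it to other genes. No chromosome was called as shifted: of 20 tested, 0 passed camera and 0 had an unadjusted p under 0.05. With an estimated correlation 0 passed. The simulated lists held 20 genes, so the power of camera for sets as large as a chromosome was not measured.

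The count of switched-on probe sets was 196, naming 153 genes, and that of switched-off ones was 172, naming 143 genes. Besides the 8 among the highest genes, Tex15, Perp, Ivl, Dsp, Esam, Nefm, Rhox6 and Dppa2 were switched on. Of the 12 lowest genes Agtr2, Mfap4, Egfl6 and Angptl1 were switched off, as was Mef2c. With the stricter limits of the 30th and 60th percentiles the counts were 53 and 37.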

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

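Of the manufacturer's control probe sets, which were left out of the comparison, 4 were called higher in treated cultures by limma, with the adjustment over the 64 control probe sets, and in each the 3 treated arrays lay above the 3 control arrays. They drew attention as signal outside the main measurement. The probe set carrying the name of a murine B2 sequence in lower case had a log2 change of 1.67, from 490.1 ± 49.5 (SD, n = 3) to 1591 ± 285. Another probe set named for B2, with a signal near the top of the scale, changed by 0.22 (adjusted p = 0.26). The 3 probe sets named for the transferrin receptor changed by 1.57 at the 3' end, 1.37 in the middle and 1.36 at the 5' end. What the B2 probe sets target is taken from their names alone, and no explanation was tested.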

How the results depend on the processing

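With the deposited signals left unscaled, 5019 probe sets passed (1977 higher, 3042 lower) and 2734 genes (1088 higher, 1646 lower), of which 4873 probe sets and 2668 genes were also called after scaling. The share higher was then 39.4% against 47.5%, and the median log2 change of all tested probe sets was -0.071 against -5.03e-05. Scaling alone differs between these settings, so the lower share comes from array levels that were not set equal. Why the levels differ between arrays was not tested. The other settings gave 7724 to 9541 probe sets apart from leaving out arrays, all within 1.5 times 9040. Leaving out each array in turn gave 7635 to 8061 probe sets and 8 to 10 lists. Lists called went from 8 to 0 with an estimated correlation and to 20 with fry. With no filter the germline median went from 2.23 to 0.27 and the list still passed (adjusted p = 0.0339). The strict filter left fewer than 5 germline genes, so that list was not tested there. Limits at the 30th and 60th percentiles left 53 probe sets switched on and 37 switched off, by construction. Of 2175 comparisons over the named genes, 2073 kept their side of the threshold, 74 lost it, 28 gained it and 0 reversed. Of 834 that left out 1 array, 44 lost it and 7 gained it. Of 410 comparisons over the lists, apart from the estimated correlation and fry, 0 lost a call and 14 gained one.

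Deviations of same-numbered cultures from their group means correlated at 0.186, 0.172 and 0.072. The highest correlation with another number was -0.034, -0.022 and -0.022. The main fit was unpaired because the sources do not say that a number stands for a shared explant. Every culture correlated best with its own number, a hint from the data and not the design. With the replicate number as a block, 9541 probe sets, 5262 genes and 8 lists passed. Of the named genes, Uhrf1, Eif2s3y and Kdm5d then passed (adjusted p = 0.0331, 0.0167 and 0.0474) and Comp and Rpl12 did not (adjusted p = 0.0519 and 0.0524). Low signals near background limit the folds of dim genes.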

Other observations

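Gene families, defined by the letters that begin a symbol, were tested after the fixed lists had been seen, and so were the genes named in this part and the tests on keratins, matrix genes, splits for chromosomes, neighbouring genes with and without the filter, and symbols sharing letters. Of 393 families, 11 passed camera and 0 passed with an estimated correlation (adjusted p = 0.859), so each is given as a description. Of 14 Psmd genes, which encode part of the regulatory particle of the proteasome, 12 rose and 0 fell (median log2 change 0.55), and of 7 Psma genes, which encode part of its core, 6 rose and 0 fell (0.47). The other proteasome families were not called: 6 of 7 Psmc genes rose and 0 fell (0.35; adjusted p = 0.0564), and 5 of 10 Psmb genes rose and 0 fell (0.28; adjusted p = 0.147). Of 7 Cct genes, which encode the cytosolic chaperonin, 6 rose and 0 fell (0.53), led by Cct7 (0.82). With the deposited signals unscaled the medians of Psmd, Psma and Cct stayed above 0 (0.48, 0.40 and 0.46), while 4, 1 and 3 members passed, and 1 each of Psmc and Psmb. Chemokines of the Ccl stem rose in 5 of 10 cases and fell in 0, led by Ccl20 (4.22), Ccl2 (3.47) and Ccl7 (2.30), while Cxcl chemokines rose in 6 and fell in 1 of 10 cases and were not called (adjusted p = 0.183). Of 13 Tnfrsf receptors 6 rose and 0 fell, with Tnfrsf12a at 1.98. The filter favours dim genes that changed: with none, 4 of 18 Ccl genes rose (median 0.55) and 7 of 19 Tnfrsf genes (0.39).

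Families that were lower included genes of the primary cilium and of matrix turnover. Of 14 Ift genes, which encode the intraflagellar transport machinery, 8 fell and 0 rose (median -0.46), among them Ift172 (-1.04), Ift80 (-0.93) and Ift57 (-0.97). Of 9 Adamts proteases 8 fell and 0 rose (median -0.82), with Adamts1 at -2.04 and Adamts5 at -1.88. Among 30 Col genes 18 fell and 5 rose (median -0.72), and with no filter 16 of 42 fell and 5 rose (-0.25). Zinc finger genes of the Zfp stem fell in 95 and rose in 10 of 256 cases (median -0.30), led by Zfp521 (-3.57). Tex genes, named for testis expression, rose in 6 of 12 cases and fell in 0, and with no filter in 6 of 35 (median 0.27). Genes whose stem is the letter H mix histones with H2 antigens and rose in 12 and fell in 2 of 28 cases (median 0.40), and with no filter in 11 and 2 of 51 (0.23). With no filter 80 of 336 Zfp genes fell and 11 rose, and 9 of 15 Adamts genes fell (-0.68). The median of each family in this paragraph kept its sign under quantile normalization and without scaling, but without scaling 55 Zfp genes fell and 8 rose, 3 Tex genes rose, 6 Ift and 7 Adamts genes fell, 16 Col genes fell and 3 rose, and 9 H genes rose and 2 fell.

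Genes of the cornified envelope, the protein shell of dead epidermal cells, rose in part. Of 19 tested, 11 rose and 0 fell (median 1.29), and with no filter 12 of 33 rose and 0 fell (median 0.49), among them Crct1 (4.37), Lce1h (4.04), Lce1f (3.98), Ivl (3.79), Sprr2h (2.95) and Prr9 (2.61). Keratinocytes among the treated cells would bring their abundant keratins, and a median rise of at least 1 would have pointed to such cells. The median change of Krt1, Krt5, Krt10, Krt14, Krt15 and Krt17 was 0.0986. The bootstrap 95% interval over these genes was -0.25 to 0.59 and leaves out the error of the arrays. Of the 2 past the filter, Krt5 changed by 0.44 and Krt10 by -0.015. These values gave no sign of such cells. They do not exclude them, since 4 of the 6 were below the filter, where the scale understates a rise. Probe sets shared between similar genes remain open: the 16 probe sets not marked as shared had a median of 1.05, where a median under 0.5 would have pointed to sharing, and the bootstrap 95% interval of 0.37 to 2.11 reached below that, although 8 of the 11 risers were measured by such probe sets. The 16 probe sets had passed the filter, which favours dim members that rose, so their median may be too high for this comparison. An effect of the drug on the cornified envelope genes may also account for the rise and was not tested.

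The fall of matrix genes was set against 2 technical explanations. For a lower share of fibroblasts in the treated cultures, the test asked whether all members fell alike. Of 25 members, 10 had a 95% interval wholly above the list median. This cannot decide the question, since a list whose changes vary has members above its own median. A lower share also need not lower all members by the same amount. RNA degradation would raise the 3' to 5' ratio of Actb, which instead differed by -0.106, treated minus control, while that of Gapdh differed by 0.0256 (exact permutation p = 0.2). A response of the cells to the treatment is a candidate explanation that stays open and was not tested.

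Genes that rose at least 2-fold lay next to one another more often than in random draws, and so did genes that fell. Among 12145 placed genes, 65 adjacent pairs with different symbol stems both rose, against 33.9 in random draws (middle 95%: 23 to 45; permutation p = 0.0001, the smallest that 10000 draws can give), and the pairs lower by 2-fold numbered 56 against 42.6 (permutation p = 0.023). The filter, which leaves out dim unchanged genes between risers, does not account for it: among all 18032 placed genes with no filter, 53 pairs stood against 30.5 in plain draws (permutation p = 0.0003) and 29.9 in draws within deciles of control signal (permutation p = 0.0002). Overlapping or abutting genes do not account for it either, since 58 pairs remained against 27.97 without those within 1000 bases (permutation p = 0.0001), and 55 against 27.9 without pairs whose symbols also share 3 letters. Among the pairs were Dppa2 (2.75) with the germ-cell gene Morc1 (2.41), and the serine proteases Gzme (2.47) and Mcpt8 (2.21). Genes lower by 2-fold also lay together with no filter, with 50 pairs against 31.3 in plain draws (permutation p = 0.001). Draws within deciles of control signal gave 34.3 (permutation p = 0.0054). Over 1000 bases apart, 42 lower pairs stood against 24.5 in plain draws (permutation p = 0.0007). Neighbouring genes that change together may reflect shared regulation, as a hypothesis, while similar genes under unlike names stay open. The same question had first been asked of genes switched on, where 0 adjacent pairs with different stems stood against 1.17 in random draws (permutation p = 1) and 2 pairs of any kind against 1.26 (permutation p = 0.4), and the wider set of genes was tried after that negative result.

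The 6 arrays make 10 splits into 3 against 3, too few for a share under 0.05. The real split gave 9040 probe sets against 0 in the highest of the others, and 5008 genes against 0. It gave 8 lists against 10, with 3 splits at 8 or more, and each other split still holds 2 arrays of one group against 1. It gave 0 chromosomes against 0, as did all 10 splits, and 368 switched probe sets against 15. For probe sets, genes and switched probe sets, 1 split, the real one, reached its count.

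The 24 poly-A spike control probe sets were all lower in treated cultures, with a median of -0.26 and 2 past the adjusted p, and 17 of 18 hybridization control probe sets were higher, with a median of 0.25. Several probe sets read each spiked transcript (dap, lys, phe and thr, and bioB, bioC, bioD and cre), so these counts are not of independent readings.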
